A study of Mus musculus with 9 samples.

How the data were processed

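RNA sequencing measured gene expression in 9 libraries of neonatal mouse cardiac fibroblasts, 3 for each of 3 groups, collected 14 days after infection with a virus. Per the labels' protocols, the cells were infected 24 h after seeding, kept in induction medium with or without the compound, and lysed for total RNA with TRIzol. The libraries were made with a directional Illumina kit, per the labels' protocols. The authors deposited 1 table of TPM values, length-corrected shares of the transcripts scaled to a common total, with 1 value per gene symbol and library. Per the submitters' processing notes, kallisto, DESeq2 and the mouse build mm9 were used. Their versions, their roles and the annotation are not given in the sources used here, nor is whether the strand of the reads was used. kallisto estimates transcript abundance by assigning reads to compatible transcripts, so the values of near-identical genes, such as the muscle actins, the myosin heavy chains or the metallothioneins, are uncertain relative to each other. Antisense partners are uncertain for the same reason as long as the strand setting is unknown.

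The TPM values of a library summed to between 988020 and 988999. TPM keeps no record of read depth, so depth is unknown here and no counting interval or detection floor is given. Because the total is fixed, a large rise of some genes lowers the share of all others. The 10 most abundant genes took between 6.54% and 7.72% of the TPM. The table held 34804 lines, of which 25 carried a date in place of a gene symbol. These held between 0.123% and 0.176% of the TPM and were left out of all tests, since the genes behind them are not identified by the table. No pair of libraries held identical values (0 pairs), and all 9 columns were used.

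Tests were run in R 4.3.3 with limma 3.58.1 on log2(TPM + 1). Genes with a mean TPM of at least 1 over all 9 libraries were kept, which left 13228 of 34779 named genes. A single linear model with the group as its only term was fitted to all 9 libraries, so that the groups share 1 estimate of the spread with 6 residual degrees of freedom. limma's moderated test used a trend of the variance with expression, two-sided, with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. The design written for this work allowed for a count model or for limma on normalized values, and the unit of the table led to limma. Log2 fold changes are differences of mean log2(TPM + 1), which understate the change of genes at low TPM. Folds are ratios of the mean TPM and are given only where both means are at least 1.

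Gene lists were tested with camera, from limma, at a preset inter-gene correlation of 0.01 and with adjustment over the lists of a comparison. The same test was repeated with a correlation estimated from the data, and fry was run beside it. Of 26 lists, 25 had at least 3 measured members. The list of Schwann and neural crest markers had 0 members above the filter and was not tested. The other lists cover the reprogramming factors, sarcomere, calcium handling and ion channels, cardiac transcription factors and hormones, fibroblast and matrix, myofibroblast and TGF-beta response, smooth muscle, skeletal muscle, MEF2 and class IIa HDAC responsive genes, histone deacetylases, 14-3-3 proteins, fatty acid oxidation, oxidative phosphorylation, glycolysis, inflammatory cytokines and chemokines, interferon response, cell cycle, p53 and senescence, endoplasmic reticulum and amino acid stress, chondrocyte and bone, and markers of macrophages, endothelium, epicardium, pericytes and adipocytes. Named genes followed a rule for each of the first 2 comparisons. It took the 10 largest rises and the 10 largest falls in log2 fold change among called genes whose groups did not overlap and whose mean TPM in the higher group was at least 17.9, leaving out predicted genes. It also took up to 4 members of each list with the smallest adjusted p, further members that the account of a list needed, the 3 delivered factors, and Hdac4, Hdac5, Hdac7 and Hdac9. Of the 10 largest rises and falls, the 1 gene with only a clone name is not described, and of the list members the text describes a part. Ftl1, Mgst1 and Slc30a1 fall outside this rule and were chosen after the values were seen. The groups, the tests of the comparisons, the 26 lists, the naming rule and the alternatives were fixed before the data were examined, except for 3 alternatives chosen after seeing the data. The closing section also uses gene sets drawn up after seeing the data, for MiT/TFE, NRF2, MTF1, epidermal and further macrophage genes. The 3 alternatives are limma array weights, removal of each library's trend with transcript length, and, for TMP269 against MGT, a fit without DsRed replicate 2. Lengths came from GENCODE release M21 (build GRCm38), matched by symbol for 13057 of the tested genes (98.7%). No coordinates are given, because that build is not the one named by the submitters.

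The analysis was tested on simulated data with 200 of 13228 genes changed by known folds. With a spread set per library, 65% of the 2-fold and 89% of the 4-fold changes were recovered for MGT against DsRed, 54% and 91% for TMP269 against MGT, and 52% and 90% for TMP269 against DsRed. Of the calls, 2.53%, 0% and 0.699% were false in these 3 comparisons. With a spread set per group and gene, 69% and 93%, 48% and 89%, and 57% and 96% were recovered. The false share was then 45.8% for MGT against DsRed, 5.52% for TMP269 against MGT and 46.5% for TMP269 against DsRed. In these comparisons 137, 8 and 133 unchanged genes were called. A false share depends on the number of changed genes, 200 here, so these shares do not carry over to the calls in the data. The spread per group and gene was the SD of 3 libraries, which is itself uncertain. A spread that differs between groups, gene by gene, therefore raises false calls in the comparisons with DsRed, and which simulation is closer to these data is not known. The simulation was first run with the spread per library alone, and the second kind was added afterwards.

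Alternatives covered the test (no trend, exact ordering of the groups), the scaling (median-ratio, quantile), the pseudocount (0.1), the filter (none, or the upper part of the genes by mean), the libraries in the fit, the replicate number as a block, each library left out in turn and a log2 fold threshold of 1. The closing section gives their effect. Genes without a line in the table, such as Myh11 and Nr4a1, were not analysed here. Genes below the filter were left out of the tests and are given as levels where named.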

Results

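Gene expression was profiled by RNA sequencing in neonatal mouse cardiac fibroblasts, the matrix-producing stromal cells of the heart, at day 14 after infection with a virus. The 9 libraries form 3 groups of 3. The negative control received a virus for DsRed, a red fluorescent protein. Cells of the MGT group received a virus for the cardiac transcription factors Mef2c, Gata4 and Tbx5, a mixture used to turn fibroblasts into cardiomyocyte-like cells. The remaining group received the MGT virus and TMP269, a small-molecule inhibitor of class IIa histone deacetylases that the labels call an HDAC4 inhibitor. The series set out to learn how TMP269 affects reprogramming by MGT. The labels number the replicates as biological ones but name no cultures or animals. The p-values of genes therefore measure the spread between these libraries, which may be technical. The camera p-values of lists set the members against all other genes, at a preset correlation of 0.01. They are too small where members of a list vary together between libraries. The estimated correlation ran from −0.288 for the reprogramming factors to 0.841 for the macrophage markers.

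Between 12370 and 13273 genes per library reached a TPM of at least 1. Read depth is unknown with this unit. Across genes, Pearson's r of log2 values between replicates lay between 0.978 and 0.981 in the MGT group, and genes are not independent replicates. DsRed replicate 2 stood apart from the other DsRed libraries, with r between 0.942 and 0.943. Its upper-quartile TPM was 5.38, against 8.69 to 9.57 in the other 8 libraries. Values below are mean TPM ± SD with n = 3 per group, log2 fold changes ± SE come from limma, and adjusted p-values are limma's for genes and camera's for lists.

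The comparison of MGT with DsRed asked what the factors changed by themselves. Contractile genes of heart and skeletal muscle rose, as did genes of calcium handling, while several fibroblast, p53 and inflammatory genes fell. All 3 delivered factors were higher. Tbx5 went from 4.55 ± 1.58 to 382.5 ± 8.9 TPM (84.1-fold), Mef2c from 16.4 ± 15.3 to 648.2 ± 46.5 (39.4-fold) and Gata4 from 62.6 ± 19.2 to 256.2 ± 18.5 (4.09-fold), with adjusted p of 3.32e-08, 3.54e-05 and 0.000138. DsRed replicate 2 had more Mef2c than the other DsRed libraries (34.2 against a mean of 7.59 TPM), and the fold was 85.4 without it. As a list they had a camera adjusted p of 7.96e-06, and an adjusted p = 0.0238 with an estimated correlation. The virus carried these genes, so the rise of this list was given by the design. It is among the lists called in both comparisons with DsRed, with the preset and with the estimated correlation. The table has 1 value per symbol and does not separate viral from endogenous transcripts.

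Sarcomere genes rose without exception: 23 of 23 measured members were called, and 23 when adjusted over the list alone (median log2 fold change 3.92, adjusted p = 1.85e-40, adjusted p = 0.00876 with an estimated correlation). Myom2, a protein of the sarcomere's M-band, rose 123-fold to 402.9 ± 20.2 TPM (log2 6.58 ± 0.15, adjusted p = 1.06e-08). Actc1, the cardiac alpha-actin, rose 107-fold to 563.5 ± 31.8 TPM, and Myl4 and Myl7, the atrial myosin light chains, rose from 73.3 ± 14.1 to 5868 ± 216 TPM and from 12.4 ± 1.2 to 794.1 ± 63.2 TPM. Myh6, the main myosin heavy chain of the adult mouse heart, rose 26.1-fold to 71.3 ± 4.3 TPM. The ventricular genes Myl2 and Myl3 stayed below the filter, at means of at most 0.589 TPM in any group. Skeletal muscle genes rose as well, in 9 of 10 measured members (9 when adjusted over the list alone, median 3.57, adjusted p = 1.61e-13, adjusted p = 0.00876 with an estimated correlation). Among them, Myh1, a fast myosin heavy chain, went from 1.30 ± 0.53 to 147.2 ± 3.6 TPM and the skeletal alpha-actin Acta1 rose 19.7-fold. Myog and Myod1, which drive skeletal myogenesis, were at means of at most 0.274 TPM.

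Of 19 measured genes for calcium handling and ion channels, 15 rose and none fell (17 when adjusted over the list alone, median 1.44, adjusted p = 1.54e-10, adjusted p = 0.0672 with an estimated correlation). With 1 library left out, the 15 became 9 without MGT replicate 1 and stayed at most 15. Sln, an inhibitor of the calcium pump, rose 80.9-fold to 149 ± 5.7 TPM, and Casq2, the calcium store of the cardiac sarcoplasmic reticulum, rose 46.4-fold to 342.5 ± 21.4 TPM. Among 12 cardiac transcription factors and hormones, 7 rose and 1 fell (7 and 2 when adjusted over the list alone, median 1.14, adjusted p = 0.00418, adjusted p = 0.0807 with an estimated correlation). Leaving out DsRed replicate 2 gave 6 higher and 3 lower. Ankrd1, a sarcomere-linked transcriptional regulator, rose 3.26-fold to 4281 ± 158 TPM and Smarcd3, a cardiac subunit of a chromatin remodelling complex, rose 2.86-fold. Nppb, a natriuretic peptide, rose 5.27-fold, whereas Nppa, its atrial relative, was at 16.7 ± 19.7 and 24.3 ± 0.8 TPM and missed the threshold (adjusted p = 0.335). That rests on DsRed replicate 2, at 39.0 TPM against a mean of 5.52 in the other DsRed libraries, and without it Nppa was called 4.40-fold higher (adjusted p = 0.00974). Hand2, a heart-field transcription factor, fell by 0.77 ± 0.14 on the log2 scale (adjusted p = 0.00461).

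**Figure D1:**
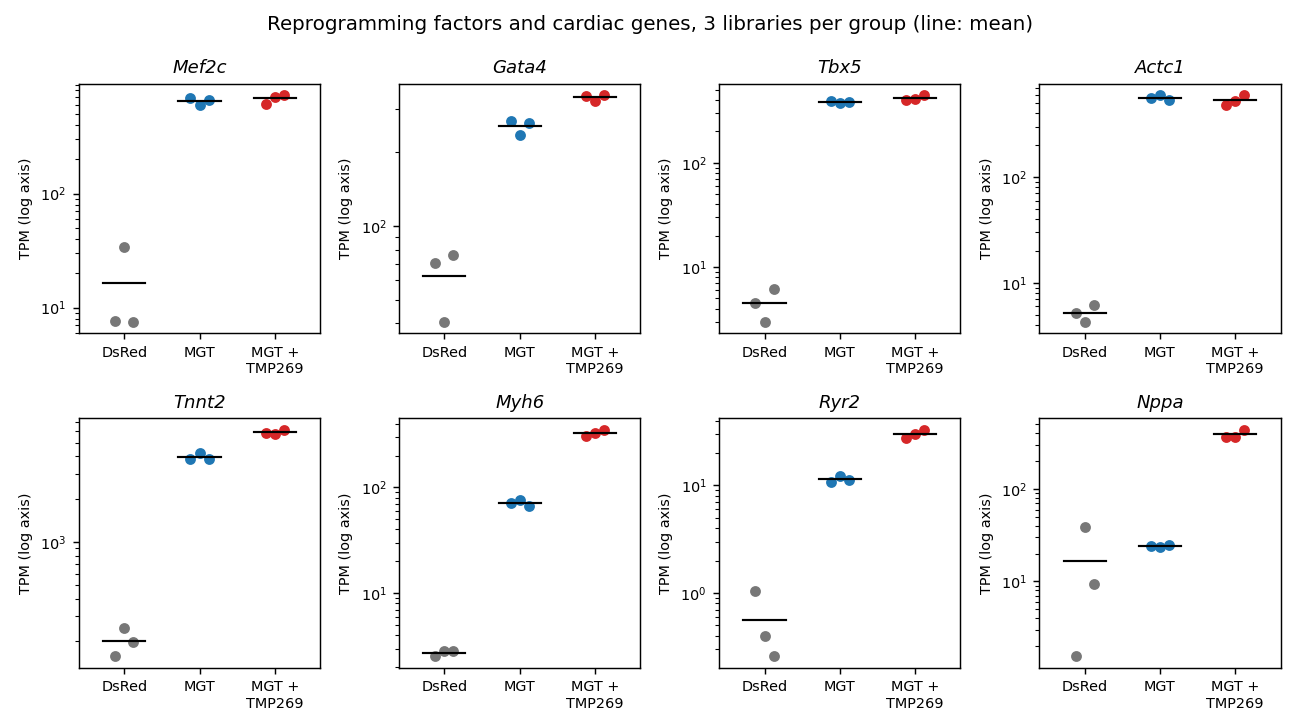
TPM of the 3 delivered factors and 5 cardiac genes on a log axis, with 3 libraries as points and the group mean as a line. Tbx5 lies near 4.55 TPM in DsRed and near 382.5 TPM in MGT, while Nppa is at 24.3 TPM in MGT and 388.6 TPM with TMP269.

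Of 30 fibroblast and matrix genes, 12 fell and 2 rose (12 and 2 when adjusted over the list alone, median −0.39, adjusted p = 6.7e-05, adjusted p = 0.514 with an estimated correlation). A fit without DsRed replicate 2 had 19 lower and 6 higher. Mmp2, a matrix metalloproteinase, fell from 662.4 ± 69.1 to 187.1 ± 12.4 TPM (3.54-fold, adjusted p = 6.75e-06), Tcf21, a transcription factor of the cardiac fibroblast lineage, fell 2.65-fold, and the proteoglycan Lum fell 7.74-fold. In the other direction, Col6a3, a collagen VI chain, rose 5.14-fold to 138.8 ± 7.6 TPM and Thy1, a fibroblast surface protein, rose 2.20-fold. The list of the myofibroblast and TGF-beta response moved upward, with 7 of 18 members higher and 1 lower (8 and 1 when adjusted over the list alone, median 0.43, adjusted p = 0.00532, adjusted p = 0.514 with an estimated correlation). Without DsRed replicate 2 it had 9 higher and 3 lower. Tgfb3, a TGF-beta ligand, rose 3.29-fold and Cthrc1, a secreted protein of activated fibroblasts, rose 1.70-fold, while Cnn1, a calponin of contractile cells, fell 1.98-fold. Smooth muscle genes went both ways, 2 higher and 3 lower of 10 (2 and 4 when adjusted over the list alone), and the list was not called (adjusted p = 0.21). Its median was −0.17, its mean 0.02 and its test pointed downward. Lower counts ran from 2 without MGT replicate 2 to 4 without DsRed replicate 2.

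Genes known to respond to MEF2 or to class IIa deacetylases included 6 higher and 1 lower of 14 (6 and 1 when adjusted over the list alone, median 0.33, adjusted p = 0.0031). The call was lost with an adjusted p = 0.514 with an estimated correlation, and with 0.076 without DsRed replicate 2. The lower gene, Klf2, was not called without any 1 of the MGT libraries or without DsRed replicate 1 (0 lower), and 2 were lower without DsRed replicate 2. Rcan1, a calcineurin regulator, rose from 31.7 ± 4.2 to 235.5 ± 7.7 TPM (7.42-fold). Xirp2 and Xirp1, actin-binding repeat proteins of striated muscle, rose to 13.3 ± 0.9 and 11.9 ± 2.4 TPM from below 1 TPM. Hdac4 itself was at 7.75 ± 3.69 TPM in DsRed and 11.2 ± 2.2 TPM in MGT (adjusted p = 0.304) and Hdac5 at 73.7 ± 21.6 and 73.4 ± 10.9 TPM (adjusted p = 0.96). Hdac9, a class IIa deacetylase, rose from 1.46 ± 1.09 to 5.49 ± 0.47 TPM (adjusted p = 0.0102). Of the 13 histone deacetylases and corepressors, 2 rose and 1 fell (2 and 1 when adjusted over the list alone), with a median of 0.07 that turned to −0.06 and −0.04 under median-ratio and quantile scaling (adjusted p = 0.924). The lower one, Hdac7, was at 43.0 ± 5.1 and 29.5 ± 2.5 TPM, and its adjusted p of 0.0388 reached 0.159 with 1 compared library left out, being lost without any 1 of MGT replicates 1, 2 and 3 or DsRed replicates 1 and 3.

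Outside these programs, Synpo2l, an actin-associated protein of striated muscle, and Mustn1, a small musculoskeletal protein, rose 85.8-fold and 51.7-fold. The largest falls included Igfbp3, which binds insulin-like growth factors, from 289.8 ± 61.9 to 16.6 ± 1.5 TPM (17.4-fold, adjusted p = 5.19e-07), and Gas1, a growth-arrest and hedgehog co-receptor gene (10.1-fold). Id1, an inhibitor of helix-loop-helix factors, fell 7.78-fold and Plac8 8.42-fold. The extracellular proteins Srpx and Cpxm1 fell 9.78-fold and 7.40-fold, the iron carrier Trf 7.04-fold and the growth factor Vegfd 6.88-fold. Of 14 p53 and senescence genes, 4 fell and none rose (4 when adjusted over the list alone, median −0.55, adjusted p = 1.36e-06, adjusted p = 0.0672 with an estimated correlation), and without DsRed replicate 2 11 fell. The cyclin-dependent kinase inhibitors Cdkn2b and Cdkn2a fell 3.01-fold and 2.69-fold. Cell cycle genes had 2 lower and 0 higher of 24 (2 when adjusted over the list alone, median −0.31, adjusted p = 0.00229, adjusted p = 0.514 with an estimated correlation), with 9 lower without DsRed replicate 2. The lower ones were Tyms, an enzyme of thymidylate synthesis (2.06-fold), and the mitotic kinase Cdk1, whose call was lost without any 1 of 5 of the 6 compared libraries (highest adjusted p 0.0813). Among 19 inflammatory cytokines and chemokines, 6 fell and 2 rose (6 and 2 when adjusted over the list alone, median −0.22, adjusted p = 0.00418, adjusted p = 0.473 with an estimated correlation). Cxcl12, a chemokine of stromal cells, fell 2.72-fold and the cytokine Il6 2.48-fold. Only 3 fell without any 1 of the MGT replicates or DsRed replicate 3, and none rose without any 1 of the MGT libraries or DsRed replicate 1. Interferon response genes moved down as a list (median −0.39, adjusted p = 0.000404, adjusted p = 0.514 with an estimated correlation, and 0.0949 without DsRed replicate 1). None of the 20 was called by limma, with 0 adjusted over the list alone and 6 lower at an unadjusted p under 0.05, and 3 were lower without DsRed replicate 3. Epicardial and mesothelial markers split, with Msln 8.82-fold higher and Gpm6a and Wt1 5.31-fold and 3.05-fold lower (3 higher and 6 lower of 10, 3 and 6 when adjusted over the list alone, median −0.83, adjusted p = 0.0235, adjusted p = 0.514 with an estimated correlation). Col10a1, the collagen of hypertrophic cartilage, went from 0.860 ± 0.302 to 138.2 ± 10.3 TPM. The chondrocyte and bone list had 2 higher and 1 lower of 8 (4 and 2 when adjusted over the list alone) and was not called (median 0.44, adjusted p = 0.351). Without DsRed replicate 3 it had 4 higher, and without DsRed replicate 2 it had 3 lower.

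Macrophage markers, which report on another cell type in the cultures, had a median of 0.83 in this comparison, with 2 of 16 called higher (5 when adjusted over the list alone, adjusted p = 0.00531, adjusted p = 0.608 with an estimated correlation). The number ran from 0 without MGT replicate 1, MGT replicate 3, DsRed replicate 1 or DsRed replicate 2 to 12 without DsRed replicate 3. The list's call was lost without DsRed replicate 1 (adjusted p = 0.104).

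In all, limma called 1630 of 13228 genes between MGT and DsRed, 1077 higher and 553 lower in MGT, and 1024 of them changed at least 2-fold (718 higher, 306 lower). The groups did not overlap for 3796 genes (28.7%), where chance gives 10%. Relative to all genes, the calls include a general shift: the median log2 fold change was 0.11, and −0.01 and −0.03 under median-ratio and quantile scaling, which moved the share of higher genes from 66.1% to 56.1% and 51.2%. The count was 3476 without DsRed replicate 2 (1652 higher, 1824 lower, 1606 of the 1630 shared), 1085 without MGT replicate 1, 1068 without MGT replicate 3, and 1066 in a fit of only these 6 libraries.

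Adding TMP269 to MGT addressed the series' main question. The natriuretic peptide genes Nppa and Nppb and a part of the cardiac contractile genes rose, and matrix genes, inflammatory genes and macrophage markers fell. The delivered factors were not called different: Mef2c was at 680.8 ± 61.8, Gata4 at 335.8 ± 10.5 and Tbx5 at 418 ± 25.1 TPM with TMP269 (limma called 0 of 3, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone, list adjusted p = 0.596). Leaving out DsRed replicate 2, 1 of them, Gata4, was called higher (log2 0.391, limma adjusted p = 0.00334). Gata4 was also called higher by limma in a fit of only the 2 groups compared (0.00345) and with array weights (0.00258).

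Of 12 cardiac transcription factors and hormones, 4 rose and 1 fell (4 and 2 when adjusted over the list alone), with a list adjusted p of 0.0827 that became 0.0452 under median-ratio scaling and 0.0432 without TMP269 replicate 1. Nppa rose from 24.3 ± 0.8 to 388.6 ± 42.3 TPM (16.0-fold, log2 3.94 ± 0.76, adjusted p = 0.0113), and Nppb from 5.89 ± 0.31 to 38.7 ± 5.1 TPM (6.56-fold, adjusted p = 4.95e-05). The other higher members, Popdc2 and Hopx, and the lower one, Smarcd3, were not called without any 1 of several compared libraries, and 2 rose in most of these fits, while 6 rose without DsRed replicate 2. Sarcomere genes had 9 higher and 1 lower of 23 (12 and 4 when adjusted over the list alone, median 0.33, adjusted p = 0.0223, adjusted p = 0.438 with an estimated correlation). The list's call was lost without DsRed replicate 2 (adjusted p = 0.212), where 12 rose and 4 fell. Without any 1 of the 6 MGT or TMP269 libraries 6 rose, and none fell without 5 of these. Myh6 rose from 71.3 ± 4.3 to 326.3 ± 23.9 TPM (4.58-fold, adjusted p = 1.97e-05), Csrp3, a mechanosensor of the Z-disc, rose 3.65-fold and Mybpc3, the cardiac myosin-binding protein, rose 3.49-fold. Actc1 and Myl4 were at 531.4 ± 54.2 and 5789 ± 216 TPM (adjusted p = 0.779 and 0.957). Calcium handling genes had 4 higher and none lower of 19 (10 and 1 when adjusted over the list alone, median 0.47, adjusted p = 0.0292, adjusted p = 0.451 with an estimated correlation), and 12 higher and 1 lower without DsRed replicate 2. Sln rose 2.90-fold to 432.4 ± 14.1 TPM and Kcnj5, a potassium channel of atrial cells, 2.95-fold. Ryr2, the cardiac ryanodine receptor, rose from 11.4 ± 0.7 to 30.1 ± 2.7 TPM (adjusted p = 0.00367, and 0.0516 at a pseudocount of 0.1). Members below the filter, not tested, went both ways. Hcn4 was at 0.232 ± 0.052 TPM in MGT and 2.43 ± 0.35 TPM with TMP269, and Gja5 at 1.3 ± 0.18 and 0.243 ± 0.11 TPM.

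Skeletal muscle genes took separate courses, 3 higher and 4 lower of 10 (3 and 4 when adjusted over the list alone, median −0.60, adjusted p = 0.0219, adjusted p = 0.204 with an estimated correlation, and 0.053 under median-ratio scaling). Myh2 fell from 43.5 ± 2.4 to 2.97 ± 0.54 TPM (14.6-fold, adjusted p = 1.16e-05) and Myh1 fell 3.84-fold, while Myl1, a myosin light chain, rose 5.01-fold to 302.8 ± 4.5 TPM. Only 1 rose without any 1 of the MGT or TMP269 libraries.

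Fibroblast and matrix genes fell in 20 of 30 cases and rose in none (25 and 0 when adjusted over the list alone, median −0.97, adjusted p = 2.56e-25, adjusted p = 0.104 with an estimated correlation). Postn, a matrix protein of activated fibroblasts, fell from 724.2 ± 12.3 to 99.8 ± 4.9 TPM (7.26-fold, adjusted p = 4.95e-05). Col6a3 fell 11.3-fold, the elastin gene Eln 11.1-fold, Dpt 8.46-fold and Col1a1 3.05-fold, from 3390 ± 193 to 1111 ± 21 TPM. Outside the list, Mfap4, a microfibril-associated glycoprotein, fell 27.6-fold to 4.70 ± 0.71 TPM. Not every fibroblast gene moved: Vim was at 4396 ± 91 and 4369 ± 92 TPM (adjusted p = 0.968). In the same libraries the macrophage markers had a median of −3.32. The myofibroblast and TGF-beta response list had 9 lower and 1 higher of 18 (10 and 2 when adjusted over the list alone, median −0.58, adjusted p = 3.2e-09, adjusted p = 0.203 with an estimated correlation). Without DsRed replicate 2 it had 3 higher, and the higher gene, Cyr61, was not called without any 1 of the MGT or TMP269 libraries. Cnn1 fell 6.72-fold, Cthrc1 4.36-fold and the smooth-muscle protein Tagln 2.00-fold. Smooth muscle genes had 7 lower and 1 higher of 10 (7 and 1 when adjusted over the list alone, median −0.98, adjusted p = 4.5e-06, adjusted p = 0.104 with an estimated correlation), with 3 lower without MGT replicate 1, MGT replicate 3 or TMP269 replicate 2. Actg2, the enteric actin, fell 4.12-fold and Mylk, the myosin light chain kinase, rose 2.92-fold. Of 8 chondrocyte and bone genes, 5 fell (5 when adjusted over the list alone, median −1.38, adjusted p = 1.71e-07, adjusted p = 0.143 with an estimated correlation). Acan, the cartilage proteoglycan, fell from 50.8 ± 2.5 to 2.54 ± 0.49 TPM, and Spp1, which macrophages also make, fell 31.8-fold, again beside the macrophage median of −3.32.

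**Figure D2:**
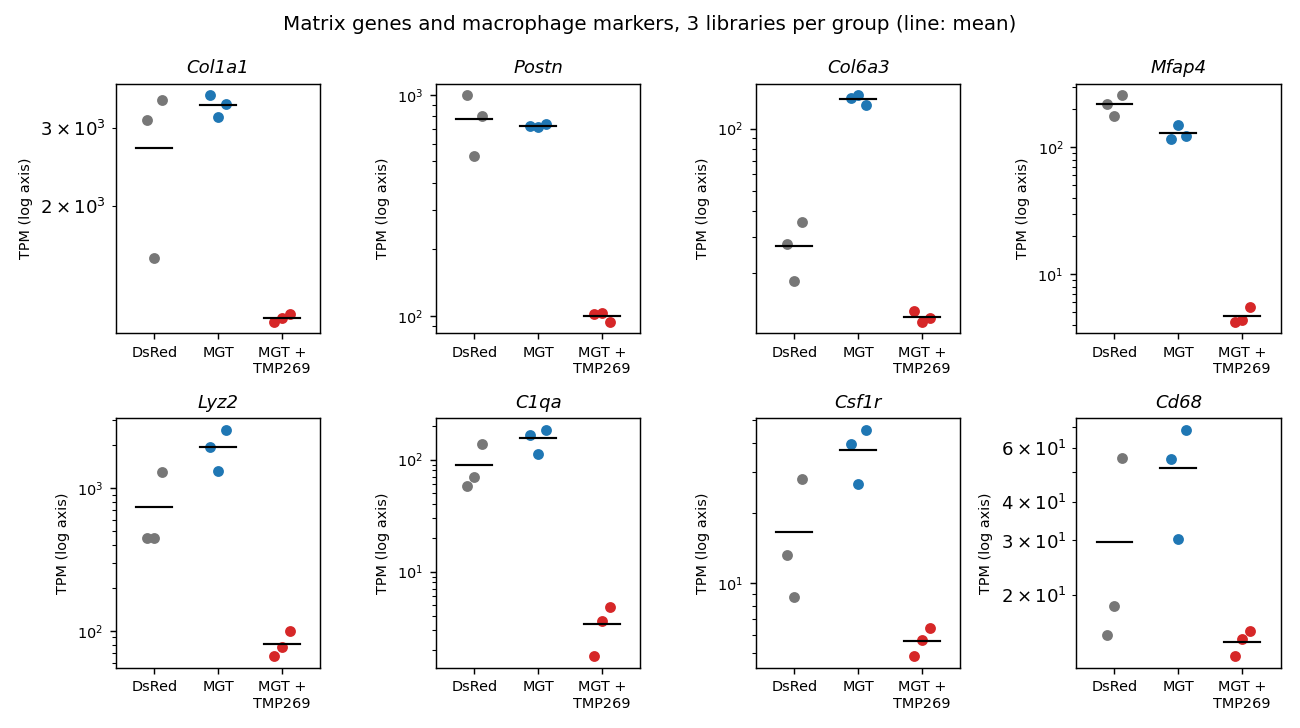
TPM of 4 matrix genes and 4 macrophage markers on a log axis, with 3 libraries as points and the group mean as a line. Postn is at 724.2 TPM in MGT and 99.8 TPM with TMP269, and C1qa is at 154.6 and 3.40 TPM.

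All 16 macrophage markers fell with TMP269 (16 when adjusted over the list alone, median −3.32, adjusted p = 4.36e-24, adjusted p = 0.143 with an estimated correlation), and at least 13 did so with any 1 of the 9 libraries left out. C1qa, a complement subunit made by macrophages, fell from 154.6 ± 37.2 to 3.40 ± 1.57 TPM (45.4-fold, adjusted p = 5.4e-05), C1qb and C1qc fell 37.7-fold and 31.5-fold and Lyz2, the macrophage lysozyme, fell 24.0-fold from 1953 ± 622 to 81.2 ± 17.3 TPM. Alox5ap, which serves leukotriene synthesis in myeloid cells, fell 33.2-fold, and the Fc receptor-like gene Fcrls and the chemokine Ccl12 fell by 4.87 ± 0.64 and 4.02 ± 0.35 on the log2 scale. Beside them, 14 of 19 inflammatory cytokines and chemokines fell and 1 rose (14 and 2 when adjusted over the list alone, median −0.90, adjusted p = 1.37e-11, adjusted p = 0.104 with an estimated correlation), and 8 fell without MGT replicate 1 or TMP269 replicate 1. 2 rose in the fit without DsRed replicate 2. The acute-phase gene Saa3 fell 3.49-fold and the monocyte chemokine Ccl2 1.86-fold, from 607.9 ± 16.1 to 326.1 ± 16.9 TPM, while Il6 rose 1.87-fold. Interferon response genes had 5 lower and none higher of 20 (11 and 0 when adjusted over the list alone, median −0.99, adjusted p = 5.1e-08, adjusted p = 0.346 with an estimated correlation, and 0.0982 by fry). None was lower without MGT replicate 1, MGT replicate 3, TMP269 replicate 1 or TMP269 replicate 2, and 11 were lower without DsRed replicate 1, again in libraries with a macrophage median of −3.32. Ifi27l2a, an interferon-induced gene outside the list, fell 23.4-fold.

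MEF2 and class IIa deacetylase responsive genes did not move as a list, with 2 higher and 3 lower of 14 (4 and 3 when adjusted over the list alone), a median of 0.17, a mean of 0.05 and a test that pointed downward (adjusted p = 0.766). Without DsRed replicate 2, 6 rose, and without MGT replicate 1, 1 fell. The list test leaves out Slc2a4 and Ppargc1a, members below the filter. Slc2a4 was at 0.24 ± 0.035 TPM in MGT and 2.07 ± 0.37 TPM with TMP269, and Ppargc1a at 0.123 ± 0.12 and 0.358 ± 0.079 TPM. Pgam2, a muscle phosphoglycerate mutase, rose 2.97-fold to 204.7 ± 8.3 TPM (adjusted p = 0.00247) and the transcription factor Klf4 rose 2.25-fold, while Rcan1 fell 3.36-fold to 70.1 ± 7.0 TPM (adjusted p = 6.41e-05). Among the deacetylases, Hdac4 was at 10.2 ± 0.5 TPM (adjusted p = 0.888) and Hdac9 at 8.77 ± 0.33 TPM (adjusted p = 0.306). limma called Hdac9 higher in a fit of only the 6 compared libraries (adjusted p = 0.0055). It also did so without DsRed replicate 2 (0.0249) and with array weights (0.00846). Hdac5 rose from 73.4 ± 10.9 to 135.8 ± 4.3 TPM (1.85-fold, adjusted p = 0.0217), and that call was lost without any 1 of the 6 compared libraries (0.0544 to 0.0956) and under median-ratio scaling (0.142). Hdac7 rose 1.47-fold with an adjusted p of 0.0412, which lay between 0.0953 and 0.174 without any 1 of the same libraries and at 0.101 under median-ratio scaling. Of the 13 deacetylases and corepressors, 2 rose (2 when adjusted over the list alone, 4 without DsRed replicate 2, 0 without any 1 of the compared libraries), with a list adjusted p of 0.309.

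**Figure D3:**
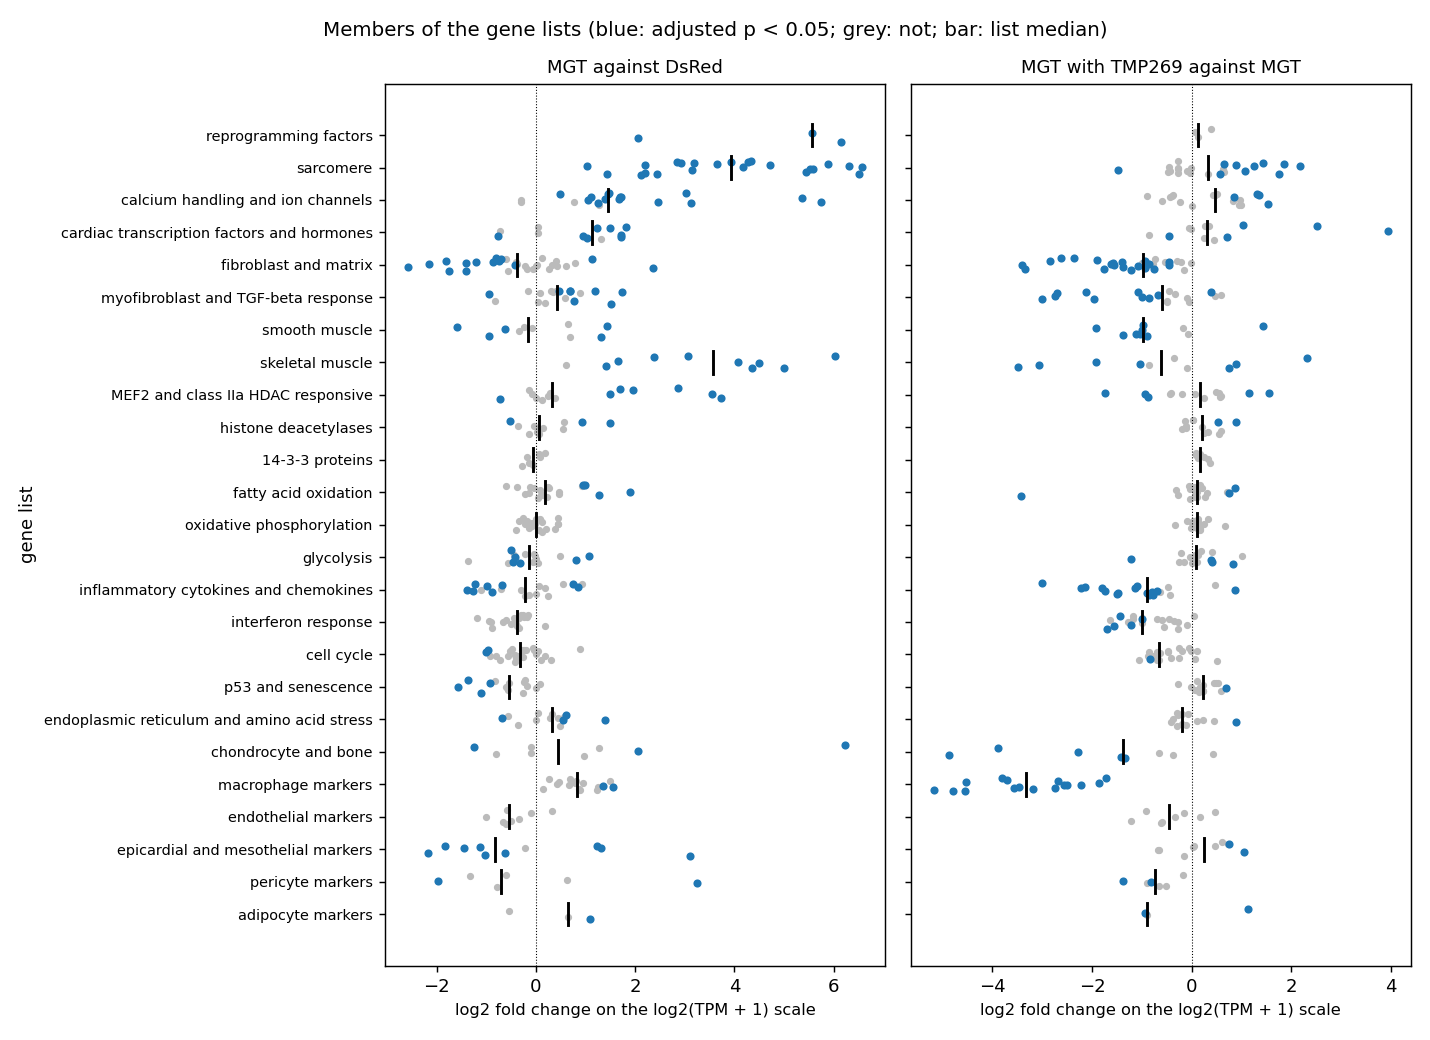
Log2 fold changes of list members for MGT against DsRed and for TMP269 against MGT, with called members in blue, others in grey and a bar at the list median. Sarcomere medians are 3.92 and 0.33, fibroblast and matrix medians −0.39 and −0.97, and macrophage medians 0.83 and −3.32.

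For TMP269 against MGT, limma called 1229 genes, 439 higher and 790 lower, with 691 at least 2-fold (164 higher, 527 lower). Groups did not overlap for 6528 genes (49.3%), where chance gives 10%. The median log2 fold change of all genes was 0.11, and 0.00 under median-ratio scaling, and the share of higher genes was 35.7%, 29.9% and 42.3% as deposited and under median-ratio and quantile scaling. DsRed replicate 2 widens the shared spread: without it 4054 genes were called (2558 higher, 1496 lower, including all 1229), and 4476 (2837 higher, 1639 lower) in a fit of only the 6 compared libraries. With 1 compared library left out the count was 635, 722 and 635 without MGT replicates 1, 2 and 3 and 650, 678 and 691 without TMP269 replicates 1, 2 and 3.

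Whether genes changed by MGT moved further or back with TMP269 was counted gene by gene. No group received TMP269 without MGT. An action of TMP269 on the MGT changes therefore cannot be told from an effect that it has without MGT. Of 1077 genes raised by MGT, 106 rose again with TMP269, 230 fell and 741 were not called. Independent lists of these sizes would share 35.7 and 64.3 genes. Of 553 genes lowered by MGT, 96 fell again, 72 rose and 385 were not called, where independent lists would share 33.0 and 18.4. Myh6, Csrp3, Sln and Nppb are among those raised in both steps, Mmp2, Eln and Actg2 among those lowered in both, and Col6a3, Acan, Myh2 and Rcan1 rose with MGT and fell with TMP269. Across genes, the log2 fold changes of the 2 steps had r = −0.13, against −0.34 in 100 simulations of unchanged groups that share the MGT libraries. The simulations hold no true changes, which widen the spread of the fold changes, so these values of r cannot be compared. The covariance of the log2 fold changes was −0.05, against −0.03 simulated, and the MGT libraries were not split between the 2 steps. Sharing them pushes the 2 steps in opposite directions, so it can add to the 230 and 72 genes that turned. In sum, 202 genes moved the same way in both steps and 302 in opposite ways. These numbers became 104 and 156 without MGT replicate 1, 109 and 179 without MGT replicate 2, 105 and 161 without MGT replicate 3, 118 and 176, 118 and 181, and 114 and 191 without TMP269 replicates 1, 2 and 3, and 693 and 1054 without DsRed replicate 2.

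**Figure D4:**
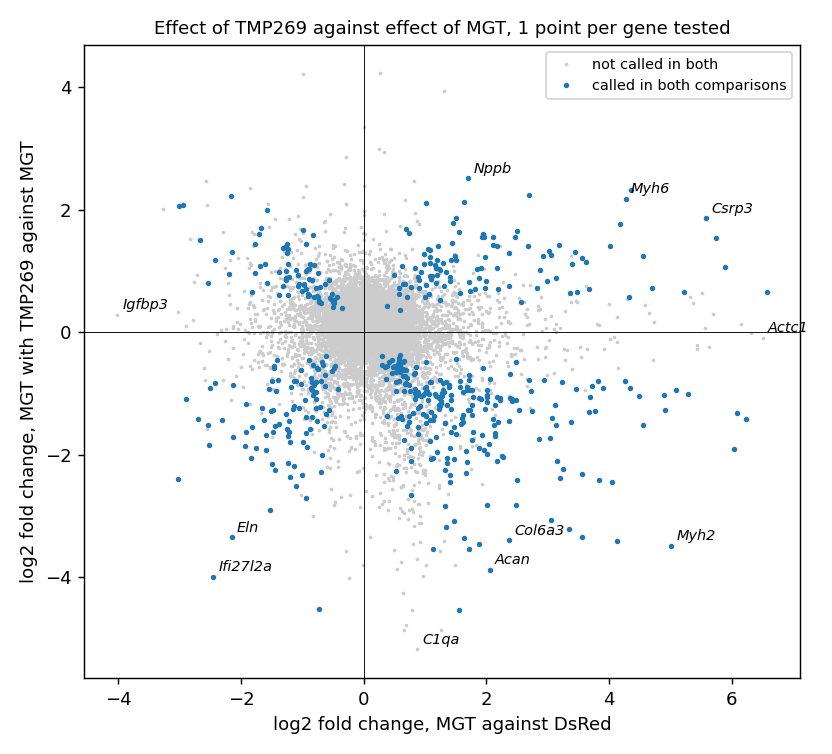
Log2 fold change with TMP269 (against MGT) plotted against that with MGT (against DsRed), 1 point per gene, with genes called in both comparisons in blue. The blue points comprise 202 genes with the same sign in both and 302 with opposite signs.

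The last comparison, TMP269 with MGT against DsRed, gave the combined difference from control cells. Sarcomere and calcium handling genes were higher and fibroblast, inflammatory, interferon and macrophage genes were lower than in control fibroblasts. Sarcomere genes rose in 22 of 23 cases (23 when adjusted over the list alone, median 4.26, adjusted p = 7.81e-29, adjusted p = 0.025 with an estimated correlation), and Myh6 was 119-fold and Nppa 23.3-fold higher (70.4-fold without DsRed replicate 2). Calcium handling genes rose in 13 of 19 (17 when adjusted over the list alone, median 1.59, adjusted p = 5.32e-10, adjusted p = 0.0573 with an estimated correlation). Of 30 fibroblast and matrix genes, 24 fell and 1 rose (25 and 1 when adjusted over the list alone, 28 and 2 without DsRed replicate 2, median −1.47, adjusted p = 2.33e-21, adjusted p = 0.0573 with an estimated correlation), with Eln 54.4-fold and Mmp2 10.5-fold lower. Inflammatory genes fell in 14 of 19 (16 when adjusted over the list alone, median −1.15, adjusted p = 1.01e-13, adjusted p = 0.0335 with an estimated correlation). Interferon response genes fell in 14 of 20 (15 when adjusted over the list alone, 7 without TMP269 replicate 1, median −1.55, adjusted p = 8.84e-11, adjusted p = 0.203 with an estimated correlation). Macrophage markers fell in 15 of 16 (15 when adjusted over the list alone, median −2.33, adjusted p = 3.61e-14, adjusted p = 0.156 with an estimated correlation) in the same libraries.

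Between these groups limma called 3016 genes, 1950 higher and 1066 lower, of which 1621 changed at least 2-fold (928 higher, 693 lower). Groups did not overlap for 5547 genes (41.9%), where chance gives 10%. The median of all genes was 0.22, and −0.01 and 0.03 under median-ratio and quantile scaling, with shares of higher genes of 64.7%, 47.1% and 50.7%. Without DsRed replicate 2 the count was 4848 (2826 higher, 2022 lower), it was 1867, 1873 and 1865 without TMP269 replicates 1, 2 and 3, and 1789 in a fit of only the 6 compared libraries.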

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

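Array weights, removal of the length trend, and the fit of TMP269 against MGT without DsRed replicate 2 were chosen after seeing the data. The order of comparisons below is MGT against DsRed, TMP269 against MGT, and TMP269 against DsRed, with 1630, 1229 and 3016 genes called. Fitting only the 2 groups compared gave 1066, 4476 and 1789 genes, where leaving out the third group changes the shared spread. Array weights, lowest for DsRed replicate 2, called 2915, 4818 and 4377 genes. The upper part of the genes by mean gave 870, 676 and 1601 and a log2 fold change of at least 1 gave 1024, 691 and 1621, both counting fewer genes by construction, and groups that do not overlap, without adjustment, numbered 3796, 6528 and 5547 (chance share 10%). With 1 library of the compared groups left out, or DsRed replicate 2 for TMP269 against MGT, the counts ran from 1068 to 3476, from 635 to 4054 and from 1865 to 4848, and among these fits the highest was without DsRed replicate 2. Libraries of the group not compared were otherwise kept for these counts. With any 1 of the 9 libraries left out, genes moving the same way in both steps ran from 104 to 693 (202 with all libraries) and those moving in opposite ways from 156 to 1054 (302 with all), for which fewer libraries and the left-out library itself are part of the construction and no other cause was tested. Median-ratio scaling gave 2070, 1530 and 3290, quantile normalization 2327, 1789 and 3461, removal of the length trend 2236, 1714 and 3531, no trend 1591, 1130 and 2960, a pseudocount of 0.1 1546, 1148 and 2949, and no filter 1571, 1159 and 2744. The replicate numbers did not pair the samples, with r between −0.07 and 0.13 in 9 same-number pairs after removal of group means, and as a block they gave 1418, 947 and 2679 genes and 16, 13 and 17 lists. Of 25 lists, 16, 13 and 17 were called, 3, 0 and 5 with an estimated correlation (7, 6 and 9 at an unadjusted p under 0.05) and 11, 12 and 17 by fry. Only the setting of the correlation differs between the camera runs, so the drop between them comes from it. By fry, the fibroblast and matrix, glycolysis, inflammatory, interferon, cell cycle, macrophage and epicardial lists were lost for MGT against DsRed. Fatty acid oxidation and chondrocyte were gained. For TMP269 against MGT, interferon and cell cycle were lost and cardiac transcription factors gained. For TMP269 against DsRed, chondrocyte and pericyte were lost, and deacetylases and fatty acid oxidation gained. For named genes, 3243 results under alternatives kept their side of the threshold, 187 lost it and 162 gained it, and for lists 978, 62 and 10. Leaving out 1 MGT library ended between 23 and 28 calls of named genes, and without DsRed replicate 2 the number was 2. The cause of the other differences was not tested. Depth is unknown with TPM, so what depth limits is not analysed here.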

Other observations

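The gene sets for MiT/TFE, NRF2, MTF1, epidermal and further macrophage genes were drawn up after the data were seen, prompted by genes found there, though before their own results. The tests of transcript length, of mixed RNA, of scaling, of batches and of the matrix genes were chosen after their results were seen, as was the minimum of 5 measured members for the epidermal list and the spread used for the matrix genes. Several genes outside the lists rose with TMP269. Mt2 and Mt1, the metallothioneins that bind zinc and copper, went from 175.6 ± 10.3 to 1291 ± 129 TPM (7.35-fold, adjusted p = 2.18e-05) and from 217.6 ± 10.9 to 1141 ± 123 TPM (5.25-fold), and their values are uncertain relative to each other. Chosen after their values were seen, Ftl1, the ferritin light chain, rose 2.28-fold to 9500 ± 321 TPM and Mgst1, a membrane glutathione transferase, rose 3.03-fold. Rragd, a GTPase of the lysosomal nutrient-sensing complex, rose 6.63-fold and Mlana, a melanosomal protein, 5.04-fold. Bex2, a small brain-expressed gene, went from 0.555 ± 0.407 to 27.8 ± 4.8 TPM (log2 4.23 ± 0.23, adjusted p = 2.18e-05). Mbd1, a methyl-CpG binding protein, fell 4.80-fold with MGT and rose 4.82-fold with TMP269, back to 121.2 ± 7.9 TPM.

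Most metabolic lists were not called. Fabp3, the heart fatty acid binding protein, rose 3.91-fold with MGT and 1.86-fold with TMP269, but the fatty acid oxidation list was not called in either step (adjusted p = 0.226 and 0.421), with 4 of 20 members higher and then 2 higher and 1 lower (4 and 1, then 3 and 1, adjusted over the list alone). The 4 became 2 without MGT replicate 3, and 2 were lower and then 4 higher without DsRed replicate 2. Its median for TMP269 was 0.10, its mean −0.01, and −0.01 was the median under median-ratio scaling. Oxidative phosphorylation had 0 of 20 called by limma in both steps (1 and 1 at an unadjusted p under 0.05, 3 and 4 higher without DsRed replicate 2, adjusted p = 0.533 and 0.421). Glycolysis fell as a list with MGT (adjusted p = 0.0367, adjusted p = 0.514 with an estimated correlation, and 0.124, 0.0669 and 0.0895 without MGT replicate 2, DsRed replicate 2 and DsRed replicate 3), with 4 lower and 2 higher of 16 (6 and 2 adjusted over the list alone). The 4 became 1 without MGT replicate 1 or 2 and 7 without DsRed replicate 2. Hk2 and Pfkp, enzymes of early glycolysis, rose 1.81-fold and 2.13-fold with MGT, and Slc16a3, a lactate exporter, fell 2.43-fold with TMP269. In that step 3 members were higher and 1 lower (3 and 1 adjusted over the list alone), with a list adjusted p of 0.735 and a median of 0.09 that turned to −0.02 under median-ratio scaling. The 3 became 0 without any 1 of the MGT or TMP269 libraries, and 4 were higher and 4 lower without DsRed replicate 2. The 14-3-3 proteins, which hold class IIa deacetylases in the cytoplasm, had 0 of 7 called by limma in both steps (0 at an unadjusted p under 0.05, 4 lower and then 3 higher without DsRed replicate 2, adjusted p = 0.315 and 0.285, and 0.029 for MGT without DsRed replicate 2). In the stress list, not called in either step (adjusted p = 0.449 and 0.31), Atf3 rose 2.98-fold with MGT and Ddit3 1.86-fold with TMP269 (adjusted p = 0.00797, and 0.108 under median-ratio scaling).

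Among markers of other cell types, the endothelial list fell with MGT and with TMP269 (adjusted p = 0.00576 and 0.0462, adjusted p = 0.0807 and 0.203 with an estimated correlation). None of its 8 members was called by limma (4 and 3 lower at an unadjusted p under 0.05, 3 and 3 without DsRed replicate 2), and the list's call for TMP269 was lost without MGT replicate 1 (0.0975), TMP269 replicate 2 (0.0795) or DsRed replicate 1 (0.0531) and under median-ratio scaling (0.0741). Pericyte markers fell with TMP269 (2 of 6 lower, 2 adjusted over the list alone, adjusted p = 0.000444, adjusted p = 0.199 with an estimated correlation), with 4 lower without DsRed replicate 2 and 1 without MGT replicates 1, 2 or 3 or TMP269 replicates 1 or 2. Mcam, a pericyte and endothelial adhesion protein, fell 2.62-fold with TMP269. With MGT the list was not called (adjusted p = 0.351), with 1 higher and 1 lower of 6 (2 and 4 adjusted over the list alone, 2 and 3 without DsRed replicate 2). The lower one, Rgs5, a pericyte signalling regulator, fell 5.88-fold. The higher one was Cspg4, with an adjusted p of at most 2.96e-05 with 1 compared library left out. Cell cycle genes fell as a list with TMP269 (median −0.64, adjusted p = 2.2e-05, adjusted p = 0.346 with an estimated correlation, and 0.0787 by fry), with 1 of 24 lower (1 adjusted over the list alone). That gene, Ccnd1, was not called without MGT replicates 1, 2 or 3 or TMP269 replicates 1 or 2, and 10 were lower without DsRed replicate 2. The p53, epicardial and adipocyte lists were not called for TMP269 (adjusted p = 0.135, 0.318 and 0.341), though p53 reached 0.0373 without DsRed replicate 2, and the adipocyte list was not called for MGT (adjusted p = 0.533). Upk1b, a mesothelial uroplakin, rose 2.09-fold with TMP269.

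Against DsRed, the group with TMP269 had higher lists for the reprogramming factors (adjusted p = 0.000116), cardiac transcription factors and hormones (0.00205), skeletal muscle (5.01e-07) and MEF2 responsive genes (0.00242), with an adjusted p = 0.0335, 0.0573, 0.0335 and 0.306 with an estimated correlation. Lists for smooth muscle (0.00191), cell cycle (3.62e-08), p53 (0.00269), chondrocyte and bone (0.00614), endothelium (0.000202) and pericytes (0.00516) were lower, with an adjusted p = 0.0842, 0.183, 0.161, 0.305, 0.0335 and 0.193 with an estimated correlation. The myofibroblast list was lower as well (median −0.01, adjusted p = 0.0156, adjusted p = 0.573 with an estimated correlation, 0.0677 under median-ratio scaling).

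For each comparison, 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real splits gave 1630, 1229 and 3016 genes and the highest others 1, 3 and 1, so that 1 of 10 splits reached the real count in each.

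DsRed replicate 2 stood apart from the other DsRed libraries, and its genes fell relative to them with transcript length (Spearman's rho −0.336 across genes, against −0.075 to 0.052 in the other 8 libraries). From the shortest to the longest of 4 length classes the median log2 ratio was −0.20, −0.24, −0.49 and −0.76. Its higher Mef2c (34.2 against 7.59 TPM) would need 4.15% of MGT RNA, and its higher Nppa (39.0 against 5.52 TPM) 178%. Tbx5, Actc1, Myl4 and Tnnt2 had a median excess of −0.18%, which argues against mixed MGT RNA as the source. Of these genes, Tnnt2 alone was in excess, at 1.84%. A loss of long transcripts in that library goes with the length trend, as a hypothesis found and tested on the same data. The shortest class was lower too (−0.20), and whether such a loss bears on Mef2c or Nppa was not tested. No biological explanation was tested.

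The fall of the macrophage markers with TMP269 is not accounted for by scaling, since their median was −3.42 after median-ratio scaling and −3.32 before. Of 15 macrophage genes outside the list, 11 were called lower and none higher (median −2.45, camera p = 1.98e-18, 0.0216 with an estimated correlation), short of the 80% set for this test, and 14 of 15 were lower, past it, under median-ratio and under quantile scaling. Fewer macrophages and lower expression in the same macrophages cannot be told apart here, because no cells were counted in the data used here. The labels name 0 batches, and a batch effect was not tested.

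The fall of the fibroblast and matrix genes was set against 2 explanations. A lower share of fibroblasts replaced alike by other cells would raise sarcomere and macrophage genes together. Their medians were 0.33 and −3.32, a difference of 3.65, and were known when this test was chosen. These values speak only to replacement by all other cells alike. They leave open a lower share of fibroblasts together with fewer macrophages. One common scaling of fibroblast genes would give equal changes only for genes far above the pseudocount and made by fibroblasts alone. The SD of the changes over the list was 4.14 times their median standard error (0.913 and 0.221). Low members such as Meox1 and Fap, at means of 1.05 and 1.37 TPM, change less on the log2(TPM + 1) scale. Abundant members changed unequally too, which the pseudocount does not account for. Postn fell further than Col1a1, and Vim was not called (means of 533, 2400 and 4270 TPM). Which of these genes other cells also make was not tested, so the unequal changes do not decide on this explanation. An effect of TMP269 on the fibroblasts themselves or on their composition stays open and was not tested.

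Hypotheses about the remaining changes with TMP269 were tested on gene lists. A rise of MiT/TFE targets, to which Rragd and Mlana belong, was tested on a list of other targets. The list median of 0.23 goes with such a rise (camera p = 0.00782, 0.314 with an estimated correlation, 3 higher and 1 lower of 20), beside a median of 0.11 over all genes. Its median was 0.12 under median-ratio scaling and 0.22 under quantile scaling. A rise of NRF2 targets, to which Mgst1 and Ftl1 belong, is consistent with a median of 0.51 (camera p = 1.05e-05, 0.0276 with an estimated correlation, 7 higher and none lower of 20), and its median was 0.41 and 0.42 under the same scalings. For a metal response through MTF1 as the source of the metallothionein rise, Slc30a1 had a log2 fold change of 0.43 ± 0.21 (adjusted p = 0.288) and decided nothing. A coordinated change of epidermal genes had a median of −0.94 and a camera p of 0.0181 as a list, which met the bound set before the test, and 0.0984 with an estimated correlation. Too few of its genes were measured to decide, 3 of 20.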
